A study of Homo sapiens with 6 samples.

How the data were processed

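The data were gene expression values from total RNA of human forebrain neuron progenitor cells at day 26, derived from H9, an established human embryonic stem cell line. A hairpin RNA against circRTN4(2,3), a circular RNA of the RTN4 gene, or a scrambled control hairpin was expressed in the cells. Per the labels' protocols, RNA was extracted with Trizol, ribosomal RNA was depleted with a RiboMinus kit, and libraries were made with the KAPA RNA HyperPrep kit. There were 6 libraries in 3 groups of 2: scramble, circRTN4 shRNA1 and circRTN4 shRNA2. The labels number the replicates and do not say whether they came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

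The deposited table held 1 FPKM value (fragments scaled by gene length and library total) per gene symbol and library, per the file headers, for 59151 genes. Per the submitters' processing notes, the tools included Trimmomatic 0.39, HISAT2 2.1.0, SAMtools 1.9 and featureCounts 2.0.1, with the human build GRCh38 (hg38). The annotation, the strand setting and the treatment of reads with several matches are not given in the sources used here. Reads of overlapping or antisense genes, and of genes with near-identical copies, therefore cannot be assigned with certainty. Gene-level FPKM mixes reads of linear and circular RNAs of a gene, so the level of the circular RNA itself was not measured. Among the symbols, 29 had been turned into dates and 4 entries carried a duplicated symbol; 3 genes of the fixed lists were not analysed here. Gene positions are those of the NCBI RefSeq annotation of GRCh38.p14 (1-based).

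Depth was read from the values. The FPKM values of low genes were multiples of a step that depends on gene length and library depth. The totals behind the FPKM values were 46634855 reads for scramble replicate 1, 77187298 for scramble replicate 2, 82353637 and 78488667 for the shRNA1 libraries, and 83629504 and 79949303 for the shRNA2 libraries. These totals came out within 0.049 of whole numbers. With a length recovered per gene, 100% of the tested genes gave numbers that were whole hundredths of a read within 0.0003 reads, and 25.9% of the read numbers were whole. Counting of reads in fractions could not be told apart from lengths recovered too short. The comparisons were therefore made on the FPKM values, with recovered reads used only in an alternative and in a test of reads on pseudogenes. Of 12594 recovered lengths that could be compared, 3574 equalled the exon union of GENCODE v29; a recovered length can be a divisor of the true one, which limits the recovered read numbers. One read on a gene of 1 kb corresponds to 0.012 to 0.0214 FPKM, and 3 reads to 0.036 to 0.064 FPKM. These values cover counting error only.

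Values were analysed as log2(FPKM + 1) without further scaling, for the 18162 genes with a mean of at least 1 FPKM over the 6 libraries. Fold changes are on this log2 scale, which understates the change of low genes. Of the tested genes, 10090 were protein-coding in GENCODE v29 and 5568 were not matched to it. Small RNA classes included 597 miRNA, 460 snRNA and 291 snoRNA genes. The median residual SD was 0.0679 for protein-coding and 0.288 for miRNA genes. limma 3.58.1 (R 4.3.3) was fitted to all 3 groups at once, with a mean-variance trend and Benjamini-Hochberg adjustment over all tested genes, and a gene was called at an adjusted p under 0.05. The comparisons were circRTN4 knockdown (the mean of both hairpins) against scramble, each hairpin against scramble, and shRNA2 against shRNA1. Depth recovery and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The design was kept as it had been fixed before the data were examined. It set the test, the gene lists and the rule for named genes.

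By that rule RTN4 and PABPC1 were always reported. For the knockdown comparison, the 12 called genes with the largest change in each direction were named if all libraries of one side lay on the same side of the other; where no such gene was called in a direction, the 5 with the smallest p were named as not passing. The other comparisons used 5 genes per direction. Clone names, small RNAs, names ending in P and 1 digit (as of pseudogenes) and similar names were counted and not named. This went by the form of the name, so it also left out the protein-coding gene CRABP1, while RPL31P61, which ends in 2 digits, was kept. Up to 4 members per list were named by the smallest p.

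The 39 fixed lists were tested with camera (preset correlation 0.01), which compares a list with all other tested genes, with Benjamini-Hochberg adjustment over the 33 lists with at least 3 tested members. The lists covered neural progenitor, forebrain patterning, ventral forebrain and interneuron, intermediate progenitor and newborn neuron, cortical excitatory neuron and pan-neuronal markers; axon guidance, presynaptic, postsynaptic and ion channel genes; Notch and Wnt pathways; cell cycle, p53, interferon, unfolded protein, heat shock, immediate early, cholesterol, and hypoxia and glycolysis genes; the RTN4 pathway, poly(A) binding and RNA export factors, and circRNA biogenesis factors; extracellular matrix genes; astrocyte, pluripotency, and choroid plexus and roof plate markers; mitochondrial mRNAs, nuclear respiratory chain, ribosomal protein and histone genes, nuclear-retained long noncoding RNAs and small structured RNAs. Lists of oligodendrocyte lineage, mesenchymal, neural crest and placode, midbrain to spinal cord, endoderm and epithelial, and endothelial and blood markers had 2, 2, 1, 1, 1 and 0 members above the filter and were not tested. Counts of list members are also given adjusted over the list alone. Numbers of list members are those above the filter, and the lists themselves were longer where low genes were left out. camera was repeated with a correlation estimated from the residuals, which here rest on 3 degrees of freedom, and with fry, which tests whether a list moves on balance in one direction without comparing it with other genes. The mean of each list was also computed per library, with the SE between libraries.

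The pipeline was tested on simulated data for 17868 genes over 10 draws, with 100 genes changed by 1.5-fold and 100 by 2-fold in each draw. For the knockdown comparison 26.7% of the 1.5-fold and 65.1% of the 2-fold changes were called, with 8.1 false calls per draw. For shRNA1 these shares were 10.6% and 47.2%, with 3.9 false calls, and for shRNA2 11.9% and 46.5%, with 5 false calls. For shRNA2 against shRNA1, where nothing had been changed, there were 0 false calls. A list of 20 genes shifted by 1.2-fold in the knockdown comparison was called in 10 of 10 draws with the preset correlation. With the estimated correlation it was called in 0 of 10. A list that did not pass with the estimated correlation may therefore still have moved. With 32 unshifted lists of random genes per draw, 1 call was made over the 10 draws. Simulated genes varied independently, and each gene had the same spread beyond counting in all groups. The draws therefore do not show how often lists of correlated genes are falsely called. The ribosomal protein list, as an example, had an estimated correlation of 0.619.

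Both hairpins were compared with the same scramble libraries, so unchanged groups with a shared control were simulated in 100 draws. All libraries, also those of scramble, were redrawn, with independent genes and the same spread per gene in every group. Alternatives covered the pseudocount, the filter, median-of-ratios and quantile scaling, the variance trend, robust hyperparameters, a minimum fold change, fits of only the compared groups, a replicate block and each library left out in turn. The following alternatives were added after the data had been seen: limma voom on the recovered read numbers, protein-coding genes of GENCODE v29 only, a correction for gene length and a crossed replicate block. A few results that the naming rule or the lists would give are not reported here.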

Results

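Gene expression was profiled in 6 ribosomal RNA-depleted total RNA libraries of forebrain neuron progenitor cells derived from H9 human embryonic stem cells, at day 26. Cells carried a scrambled hairpin or 1 of 2 hairpins against circRTN4(2,3), a circular RNA made from the RTN4 gene, with 2 libraries per group. The series as a whole concerned the export of circular RNAs by the poly(A)-binding protein PABPC1 and the function of these RNAs in neurons, and these libraries were made to study what circRTN4(2,3) does. The totals behind the FPKM values were 46634855 reads in scramble replicate 1 and 77187298 to 83629504 reads in the other 5 libraries. The scramble libraries were less alike than the libraries of either hairpin: the median SD between replicates on the log2 scale was 0.109 for scramble, 0.036 for shRNA1 and 0.045 for shRNA2. The fit shared 1 estimate of the spread per gene over the groups. The p-values against scramble therefore tended to be too small, and those between the hairpins too large. Small structured RNAs held 17.7% of the summed FPKM in scramble replicate 1, 27.5% in scramble replicate 2 and 21% to 24% in the knockdown libraries. The first principal component (34.1% of the variance) separated the groups, and the second (30.1%) held the scramble replicates apart, at 20.93 and -16.22.

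RTN4, the host gene of the targeted circular RNA, which encodes the endoplasmic reticulum protein reticulon 4 (Nogo), lies on chromosome 2 at 54972189 to 55137831. Its level was 40.3 and 38.5 FPKM in the scramble libraries, 34.2 and 34.7 FPKM with shRNA1, and 31.2 and 31.3 FPKM with shRNA2. All 4 knockdown libraries lay below both scramble libraries, with a log2 fold change of -0.26 ± 0.044 (SE) for the knockdown as a whole. This difference did not pass the threshold (limma with Benjamini-Hochberg adjustment, adjusted p = 0.135), nor did -0.19 with shRNA1 (adjusted p = 0.419) or -0.33 with shRNA2 (adjusted p = 0.0756). Without scramble replicate 1, RTN4 in the knockdown was at -0.22, and after quantile normalization it was -0.09. Gene-level FPKM mixes linear and circular reads, so these values do not measure how far the circular RNA was depleted. PABPC1 (chromosome 8, 100702916 to 100722088) stood at 44.8 ± 1.86 FPKM in scramble, 39.9 ± 0.986 with shRNA1 and 38.1 ± 1.18 with shRNA2 (mean ± SD, n = 2 each). Its log2 fold change was -0.20 for the knockdown (limma with Benjamini-Hochberg adjustment, adjusted p = 0.225), -0.16 with shRNA1 (adjusted p = 0.521) and -0.23 with shRNA2 (adjusted p = 0.149).

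In the knockdown comparison, which takes the mean of both hairpins, a small set of genes was lower than in scramble. Among them were genes of the dorsal midline of the forebrain, of Wnt signalling and of the extracellular matrix. The lists of these genes did not pass with an estimated correlation (camera adjusted p = 0.337 each). TTR, which encodes transthyretin, the thyroid hormone carrier made by the choroid plexus, averaged 6.33 ± 0.429 FPKM in scramble, 0.641 ± 0.204 with shRNA1 and 0.0605 ± 0.00391 with shRNA2 (mean ± SD, n = 2 each). COL3A1, a fibrillar collagen gene, fell from 3.33 ± 0.234 FPKM to 0.507 ± 0.0441 and 0.0625 ± 0.0234. RSPO2, a secreted amplifier of Wnt signalling, fell from 5.98 ± 0.266 FPKM to 1.62 ± 0.128 and 1.19 ± 0.22. WNT8B, a Wnt ligand of the cortical hem, fell from 4.61 ± 0.0945 FPKM to 1.53 ± 0.00196 and 2.8 ± 0.0468, and WLS, needed for the secretion of Wnt ligands, from 8.84 ± 0.662 FPKM to 4.07 ± 0.0711 and 5.19 ± 0.11. GJA1, a gap junction gene of astrocytes and radial glia, fell from 10.8 ± 0.475 FPKM to 3.86 ± 0.00158 and 5.5 ± 0.131.

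**Figure D1:**
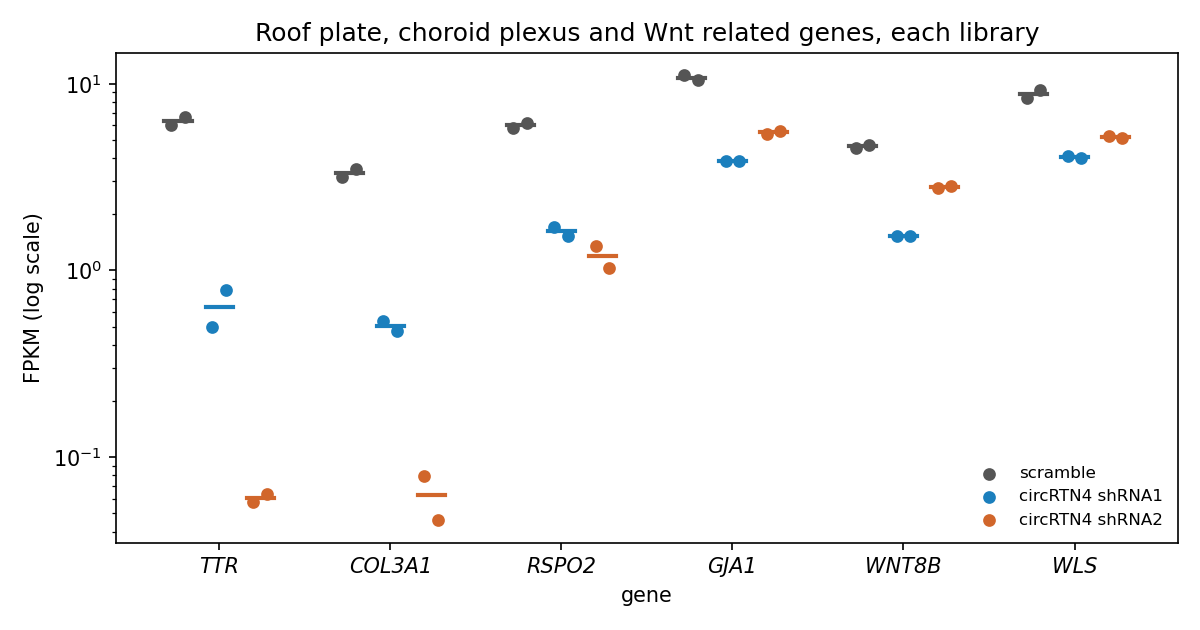
FPKM on a log axis of 6 roof plate, choroid plexus, matrix and Wnt related genes in each library; points are libraries and bars are means of the 2 libraries of a group (scramble, circRTN4 shRNA1, circRTN4 shRNA2). All 4 knockdown libraries lie below both scramble libraries for each gene, for TTR at 0.641 FPKM on average with shRNA1 and 0.0605 FPKM with shRNA2 against 6.33 FPKM in scramble. The naming rule allowed only genes whose libraries lay apart in this way.

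Of 18162 genes tested, 1 was higher and 14 were lower in the knockdown comparison (limma, Benjamini-Hochberg adjusted p under 0.05), and 2498 had an unadjusted p under 0.05. Protein-coding genes tested alone, an alternative chosen after the data were seen, gave 28 higher and 74 lower. The knockdown libraries did not overlap the scramble libraries in 18.5% of all tested genes, in either direction, against 13.3% by chance. The log2 fold changes of the genes above were -2.48 ± 0.091 for TTR (SE, limma with Benjamini-Hochberg adjustment, adjusted p = 0.00761), -1.77 ± 0.064 for COL3A1 (adjusted p = 0.00761), and -1.55 ± 0.079 for RSPO2 (0.0208). They were -1.07 ± 0.047 for GJA1 (0.013), -0.86 ± 0.046 for WNT8B (0.0208) and -0.81 ± 0.056 for WLS (0.0353). TTR and COL3A1 with shRNA2 were near the level of 3 reads on a gene of 1 kb, 0.036 FPKM. On a longer gene the same FPKM stands for more reads. The other 6 named genes that fell were SULF1, an extracellular sulfatase acting on heparan sulfate (-1.08), PLS3, an actin-bundling protein (-0.98, adjusted p = 0.05 after rounding), and NR2F1, a nuclear receptor that patterns the cortex (-0.87). They also included EEF1A1, a translation elongation factor (-0.70), BCL11B, a transcription factor of deep-layer and striatal neurons (-0.69), and FGFR2, a growth factor receptor of neural progenitors (-0.59). BCL11B averaged 11.2 FPKM in scramble, 9.74 with shRNA1 (log2 fold change -0.18, adjusted p = 0.441) and 4.32 with shRNA2. EEF1A1 averaged 209 FPKM in scramble, 180 with shRNA1 and 91.8 with shRNA2. It has near-identical pseudogenes with which it can share reads, and the copy EEF1A1P5 moved with it in shRNA2 (log2 fold change -1.17). The remaining 3 called genes fell outside the naming rule and were chosen after their values were seen. CRABP1, which encodes a retinoic acid binding protein (-2.37, adjusted p = 0.0208), and MIR3606 (-2.30) were lower, and SNORD116-30 (0.89) was higher. No nameable gene rose. The 5 with the smallest p, none of which passed, were RPL31P61, a ribosomal protein pseudogene (0.66, adjusted p = 0.0526), GNRH1, the gonadotropin-releasing hormone gene (0.51, 0.0526), and SCGN, a calcium-binding protein gene (0.64, 0.0575). The others were CAPN6, of the calpain family (0.48, 0.058) and PCDHB15, a clustered protocadherin gene (0.49, 0.0655).

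TTR lies on chromosome 18 at 31591877 to 31598821, COL3A1 on chromosome 2 at 188974373 to 189012746, RSPO2 on chromosome 8 at 107899316 to 108083620 and GJA1 on chromosome 6 at 121435646 to 121449727. WNT8B lies on chromosome 10 at 100463009 to 100483744, WLS on chromosome 1 at 68098459 to 68232546, BCL11B on chromosome 14 at 99169287 to 99272197 and EEF1A1 on chromosome 6 at 73515750 to 73521032.

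Among the lists fixed beforehand, choroid plexus and roof plate markers and Wnt pathway genes were lower in the knockdown. Of 17 choroid plexus and roof plate markers, 7 were above the filter. Of these, 2 fell (TTR and RSPO2), and 5 fell when adjusted over the list alone, adding RSPO3 (-0.72), BMP7 (-0.45) and BMP6 (-0.22). The median log2 fold change was -0.45 (camera adjusted p = 3.6e-05; adjusted p = 0.337 with an estimated correlation), and without scramble replicate 2 it was -0.25 (camera adjusted p = 0.0563). The list of Wnt pathway targets and antagonists also held ligand, amplifier and secretion genes. Its median therefore does not give the direction of Wnt signalling. Of the 27 genes in this list, 12 were above the filter. Of these, 3 fell over all genes (RSPO2, WNT8B and WLS) and 9 when adjusted over the list alone, among them SFRP2, a secreted Wnt antagonist (-0.84). All 12 values were negative, with a median of -0.37 (camera adjusted p = 1.3e-11; adjusted p = 0.337 with an estimated correlation). RSPO2 and RSPO3 belong to both lists. Of 20 extracellular matrix genes, 1 fell over all genes (COL3A1) and 6 when adjusted over the list alone, with SPARC at -0.47 and FBN2 at -0.32. The median was -0.12 (camera adjusted p = 0.000848; adjusted p = 0.337 with an estimated correlation), and -0.05 without scramble replicate 2 (camera adjusted p = 0.257).

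Ribosomal protein genes were lower by a small amount, but their list did not pass with an estimated correlation. All 74 had negative values, with a median of -0.25 and a mean of -0.24 ± 0.075 (SE between libraries). Of these, 0 passed over all genes and 43 fell when adjusted over the list alone, among them RPL17 (-0.31), RPS23 (-0.28) and RPL11 (-0.32). The list was called with camera (adjusted p = 9.3e-23; adjusted p = 0.337 with an estimated correlation). The median of the ribosomal protein genes was -0.16 without scramble replicate 2, -0.34 without scramble replicate 1 and -0.12 after quantile normalization. Cell cycle genes, 37 of 38 of them negative, had a median of -0.16 with 0 genes passing over all genes or over the list alone (camera adjusted p = 1.61e-07; adjusted p = 0.202 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, stood at -0.25 and PCNA, the replication clamp, at -0.25. Of 23 neural progenitor markers, FGFR2 fell over all genes and 8 fell when adjusted over the list alone, including PAX6 (-0.34), VIM (-0.33) and FGFR3 (-0.43). The median was -0.10 (camera adjusted p = 0.00274; adjusted p = 0.337 with an estimated correlation). Without scramble replicate 2 the progenitor call was lost (-0.08, camera adjusted p = 0.146). Of 16 pluripotency markers, 6 were above the filter. Of these, 0 passed over all genes and 4 rose when adjusted over the list alone: LIN28A (0.65), DPPA4 (0.51), SALL4 (0.30) and DNMT3B (0.16). Their list had a median of 0.24 (camera adjusted p = 9.53e-07; adjusted p = 0.202 with an estimated correlation).

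The 5 other lists called with camera had no member past the threshold over all genes. Nuclear respiratory chain genes had a median of -0.13, and 2 of 36 fell when adjusted over the list alone (NDUFA8, -0.26, and UQCR10, -0.23; adjusted p = 0.607 with an estimated correlation). Of 16 voltage-gated ion channel genes, with a median of 0.05, 1 rose when adjusted over the list alone (SCN9A, 0.31; adjusted p = 0.337 with an estimated correlation). No member passed over the list alone among 28 replication-dependent histone genes (median -0.19; adjusted p = 0.745 with an estimated correlation), 17 hypoxia and glycolysis genes (-0.12; adjusted p = 0.337) and 16 circRNA biogenesis and decay factors (-0.10; adjusted p = 0.337). Without scramble replicate 2 the calls of the histone genes (median 0.045), the nuclear respiratory chain genes (-0.02), hypoxia and glycolysis (-0.06) and voltage-gated ion channels (0.12) were lost. Without scramble replicate 1 those of voltage-gated ion channels (0.008) and circRNA biogenesis and decay factors (-0.12) were lost. Scramble replicate 1, with 17.7% of its FPKM on small structured RNAs against 27.5% in scramble replicate 2, also had the lowest depth. In all, 12 of 33 lists were called, 10 lower and 2 higher, and fewer among genes with a mean of at least 5 FPKM. With an estimated correlation 0 were called, and fry called 15.

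The other 21 lists were not called in the knockdown comparison. Medians were -0.06 for 13 forebrain patterning factors, of which NR2F1 fell over all genes and 5 fell when adjusted over the list alone (NR2F1, NR2F2, OTX1, EMX2 and FEZF2; camera adjusted p = 0.17). They were -0.05 for ventral forebrain and interneuron markers (0.509), -0.12 for intermediate progenitor and newborn neuron markers (0.517) and -0.06 for the cortical excitatory neuron markers (0.881), where 3 rose and 4 fell when adjusted over the list alone. They were -0.002 for pan-neuronal markers (camera adjusted p = 0.275), -0.09 for axon guidance and neurite outgrowth genes (0.235) and -0.01 for presynaptic genes (0.74). Further medians were 0.03 for postsynaptic genes and neurotransmitter receptors (0.0667) and -0.06 for the Notch pathway (0.17). Stress lists had medians of -0.02 for p53 targets (0.997), -0.13 for the interferon response (0.0667) and -0.06 for the unfolded protein and integrated stress response (0.517). They were -0.11 for cytosolic heat shock (0.0631), -0.004 for immediate early genes (0.712) and -0.05 for cholesterol synthesis (0.235). The RTN4 (Nogo) pathway and reticulon family had a median of -0.07 (0.394) and poly(A) binding and RNA export factors -0.08 (0.0787). Medians were -0.06 for astrocyte markers (0.232), -0.14 for mitochondrially encoded mRNAs (0.0787), 0.02 for nuclear-retained long noncoding RNAs (0.356) and -0.09 for abundant small structured RNAs (0.712). The astrocyte list held GJA1, which fell over all genes. For pan-neuronal markers, presynaptic genes, p53 targets and immediate early genes the median was negative while camera pointed higher.

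The number of genes changed, circRTN4 knockdown vs scramble, depended on single libraries: it was 494 without scramble replicate 1, 1 without scramble replicate 2, 1 without either shRNA1 library and 0 without either shRNA2 library. With 1 scramble library left, the spread came only from the hairpin libraries, so those counts do not measure the spread of scramble. Scaling by median of ratios gave 10 higher and 18 lower genes and quantile normalization 12 higher and 18 lower, against 1 and 14 without further scaling.

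With shRNA1 alone, the genes that fell were TTR, COL3A1, GJA1, WNT8B and RSPO2, each in both libraries against both scramble libraries, as the naming rule required. The list of cell cycle genes stood lower and those of neurons and synapses slightly higher by camera; with an estimated correlation only the cell cycle list passed (adjusted p = 0.0454). The log2 fold changes were -2.16 for TTR, -1.52 for COL3A1, -1.28 for GJA1 and -1.15 for WNT8B (limma with Benjamini-Hochberg adjustment, adjusted p = 0.0169 each), and -1.41 for RSPO2 (adjusted p = 0.0466). CRABP1 (-2.35), outside the naming rule and named after its value was seen, was the other called gene. In all, 0 genes were higher and 6 lower with limma, and 1630 genes had an unadjusted p under 0.05, with 3 higher and 17 lower by voom. The 5 nameable genes with the smallest p among the higher ones did not pass. They were SCGN (0.69, adjusted p = 0.129), RPL31P61 (0.64, 0.129), GAD1, which encodes an enzyme of GABA synthesis (0.50, 0.146), COPG2, a coat protein gene of Golgi vesicles (0.39, 0.183) and C22orf42 (0.53, 0.19). Leaving out any 1 library left 0 or 1 gene called.

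Cell cycle and proliferation genes were lower with shRNA1 in all 38 cases, with a median of -0.23 and 22 that fell when adjusted over the list alone. These included RRM2 (-0.32), TPX2, a spindle assembly factor (-0.29), FEN1, a DNA repair nuclease (-0.46), and MCM6, a subunit of the replicative helicase (-0.34). This list was the only one of 33 called with an estimated correlation (camera adjusted p = 1.39e-21; adjusted p = 0.0454 with an estimated correlation); 0 of its members passed over all genes. Of the neuronal lists, 5 were called as higher, with medians of 0.14 for 26 presynaptic genes (camera adjusted p = 1.66e-07; adjusted p = 0.156 with an estimated correlation) and 0.13 for 25 postsynaptic genes and receptors (2.06e-06; adjusted p = 0.156). They were 0.16 for 16 ion channel genes (5.47e-05; adjusted p = 0.156), 0.11 for 26 pan-neuronal markers (1.39e-06; adjusted p = 0.198) and 0.08 for 13 ventral forebrain and interneuron markers (0.0381; adjusted p = 0.625). When adjusted over each list alone, GRIA1 (0.37) and GRIN2B (0.35), both glutamate receptor subunit genes, rose among the postsynaptic genes, CELF4 (0.38) among the pan-neuronal markers, and GAD1 and GAD2 among the interneuron markers. With limma, 0 rose among the presynaptic and ion channel genes. Cortical excitatory neuron markers (median -0.02, camera adjusted p = 0.192) and intermediate progenitor and newborn neuron markers (-0.01, 0.879) were not called with shRNA1. The call of the ventral forebrain and interneuron markers was lost without scramble replicate 1 (median 0, camera adjusted p = 0.531), shRNA1 replicate 1 (0.185), shRNA2 replicate 1 (0.0718) or shRNA2 replicate 2 (0.0734).

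Of the choroid plexus and roof plate markers, 2 of 7 fell over all genes and 5 when adjusted over the list alone with shRNA1, with a median of -0.48 (camera adjusted p = 4.59e-09; adjusted p = 0.198 with an estimated correlation). Of 12 Wnt pathway genes, 2 fell over all genes and 8 when adjusted over the list alone, with a median of -0.41 (camera adjusted p = 3.4e-14; adjusted p = 0.198 with an estimated correlation). Of 20 extracellular matrix genes, COL3A1 fell over all genes and 8 fell when adjusted over the list alone, with a median of -0.19 (camera adjusted p = 2.8e-11; adjusted p = 0.156 with an estimated correlation). Progenitor markers (median -0.14, 2 of 23 lower when adjusted over the list alone: FGFR2 and PAX6), forebrain patterning factors (-0.08, 5 of 13), ribosomal protein genes (-0.16, 0 of 74) and histone genes (-0.23, 0 of 28) were also called as lower, with adjusted p of 0.198, 0.368, 0.368 and 0.51 with an estimated correlation. The median of the ribosomal protein genes was -0.06 without scramble replicate 2 and -0.07 after quantile normalization. The call of the patterning factors and that of the histone genes were each lost without scramble replicate 2, with medians of -0.04 and 0.012. Among genes with a mean of at least 5 FPKM, camera pointed higher for the patterning factors and the Notch pathway. Lists called with 0 members past the threshold over the list alone were the Notch pathway (-0.07), interferon response (-0.11) and heat shock (-0.07, but 0.002 after quantile normalization). They were also hypoxia and glycolysis (-0.07), poly(A) binding and RNA export (-0.06), circRNA biogenesis and decay (-0.10) and nuclear respiratory chain genes (-0.06) as lower, and immediate early genes (0.15) and pluripotency markers (0.11) as higher. Their adjusted p with an estimated correlation lay between 0.198 and 0.697. In all, 22 lists were called with shRNA1, 15 lower and 7 higher, and fry called 14. Fewer were called among genes with a mean of at least 5 FPKM. Without scramble replicate 1 the calls of the interferon response (-0.05), cytosolic heat shock (-0.08), immediate early genes (0.01) and poly(A) binding and RNA export factors (-0.05) were lost. Without scramble replicate 2 those of the Notch pathway (0.13), nuclear respiratory chain genes (0.069), hypoxia and glycolysis (-0.04), pluripotency markers (0.06) and poly(A) binding and RNA export factors (-0.05) were lost. Without shRNA1 replicate 2 the calls of the Notch pathway (-0.01), cytosolic heat shock (-0.08), immediate early genes (0.12), hypoxia and glycolysis (-0.07), pluripotency markers (0.11), nuclear respiratory chain genes (-0.04) and poly(A) binding and RNA export factors (-0.05) were lost. The heat shock and poly(A) calls were also lost without shRNA1 replicate 1 (-0.04 each), and with the Notch call without either shRNA2 library, where only the spread and the set of genes tested changed.

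With shRNA2 alone, more genes changed: 34 rose and 80 fell (limma, Benjamini-Hochberg adjusted p under 0.05; unadjusted p under 0.05 for 3496). Pluripotency markers were among the genes that rose, and axon guidance genes, the interneuron gene SST and the elongation factor gene EEF1A1 among those that fell, together with choroid plexus and Wnt genes. LIN28A, an RNA-binding protein that blocks let-7 microRNA maturation, rose from 2.26 ± 0.259 to 5.77 ± 0.186 FPKM, and DPPA4, a marker of pluripotent cells, from 2.72 ± 0.272 to 5.77 ± 0.248 FPKM (mean ± SD, n = 2). BCL11B fell from 11.2 ± 0.407 to 4.32 ± 0.152 FPKM, and SST, the somatostatin gene of interneurons, from 2.94 ± 0.756 to 0.455 ± 0.0282 FPKM.

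The 5 nameable genes with the largest rise were LIN28A (log2 fold change 1.05 ± 0.073, SE; limma with Benjamini-Hochberg adjustment, adjusted p = 0.0244), FRZB, a secreted Wnt antagonist (1.01, 0.0353), FGF19, a growth factor (0.94, 0.0496), NPY2R, a neuropeptide Y receptor (0.89, 0.0353), and DPPA4 (0.87, 0.0353). LIN28A lies on chromosome 1 at 26410817 to 26429728, and SST on chromosome 3 at 187668912 to 187670394. The 5 nameable genes with the largest fall were TTR (-2.79 ± 0.105, adjusted p = 0.00867), COL3A1 (-2.03, 0.00867), RSPO2 (-1.68, 0.0182), SST (-1.43, 0.0496) and BCL11B (-1.196 ± 0.053, 0.0139). CRABP1 (-2.39, adjusted p = 0.0234), outside the naming rule and named after its value was seen, also fell. The number of genes changed, shRNA2 vs scramble, was 2412 without scramble replicate 1 and 492 without scramble replicate 2. It was 1 without either shRNA1 library and 0 without either shRNA2 library. The counts with 1 scramble library left rest on the spread of the hairpin libraries only. Median-of-ratios scaling gave 43 higher and 48 lower genes, quantile normalization 37 and 34, and a correction for gene length 33 and 40.

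Of 16 pluripotency markers, 6 were above the filter. Of these, 3 rose with shRNA2 over all genes (LIN28A, DPPA4 and SALL4) and 4 when adjusted over the list alone, adding DNMT3B (0.28). The median was 0.41 (camera adjusted p = 4.35e-08; adjusted p = 0.301 with an estimated correlation). Of 36 axon guidance and neurite outgrowth genes, 1 rose and 6 fell over all genes, and 3 rose and 15 fell when adjusted over the list alone. SEMA3C, a secreted semaphorin, stood at -1.19, EPHA3, an ephrin receptor gene, at -0.77, PLXNA2, a semaphorin receptor gene, at -0.72 and SLIT2 at -0.52. The list's median was -0.16 (camera adjusted p = 0.0199, and 0.51 with an estimated correlation), and its call was lost without scramble replicate 2 (-0.10). Among genes with a mean of at least 5 FPKM, camera pointed higher for this list. Of 26 presynaptic genes, SYT4, a synaptotagmin gene, fell over all genes (-0.79) and 4 fell when adjusted over the list alone, with CPLX1, CPLX2 and SV2A. The median was -0.16 (camera adjusted p = 0.00511; adjusted p = 0.51 with an estimated correlation).

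Of 7 choroid plexus and roof plate markers, 3 fell with shRNA2 over all genes (TTR, RSPO2 and RSPO3), and 1 rose and 5 fell when adjusted over the list alone, the one that rose being OTX2 (0.30). The median was -0.41 (camera adjusted p = 0.00359; adjusted p = 0.51 with an estimated correlation). Without scramble replicate 1 or 2 the list's camera adjusted p was 0.127 or 0.173. Of 12 Wnt pathway genes, 5 fell over all genes and 8 when adjusted over the list alone, with a median of -0.32 (camera adjusted p = 4.35e-08; adjusted p = 0.51 with an estimated correlation). FRZB, a Wnt antagonist outside this list, rose (1.01). Of 74 ribosomal protein genes, all with negative values, 55 fell when adjusted over the list alone. The median was -0.34 (camera adjusted p = 5.33e-21; adjusted p = 0.51 with an estimated correlation), and -0.16 after quantile normalization. Nuclear respiratory chain genes had a median of -0.22, with 4 of 36 lower when adjusted over the list alone (adjusted p = 0.72 with an estimated correlation), and hypoxia and glycolysis genes -0.15 with 0 of 17 (adjusted p = 0.51 with an estimated correlation). Mitochondrially encoded mRNAs had a median of -0.25 with 0 of 13 passing (adjusted p = 0.759 with an estimated correlation), but 0.028 after quantile normalization. Cell cycle genes (median -0.07, camera adjusted p = 0.651), extracellular matrix genes (-0.04, 0.651, although 2 fell over all genes) and neural progenitor markers (-0.07, 0.346) were not called with shRNA2. In all, 9 lists were called with shRNA2, 8 lower and 1 higher, and fry called 22. Fewer were called among genes with a mean of at least 5 FPKM and among protein-coding genes alone. Without scramble replicate 2 the calls of nuclear respiratory chain genes (-0.07) and hypoxia and glycolysis (-0.11) were lost, the latter also without shRNA2 replicate 2 (-0.13). That of the mitochondrially encoded mRNAs was lost without scramble replicate 1 (-0.16), shRNA2 replicate 1 (-0.22) or either shRNA1 library (camera adjusted p = 0.0772 and 0.0741).

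Both hairpins together called 6 genes in the same direction: COL3A1, CRABP1, GJA1, RSPO2, TTR and WNT8B, all lower. Independent lists of these sizes would share 0.0264 lower genes. Simulated unchanged groups with a shared simulated scramble group shared 0 in each of 100 draws. Leaving out 1 library at a time left 0 or 1 shared gene. Across the 18162 genes, which are not independent replicates, the log2 fold changes of the hairpins correlated at r = 0.572, against 0.499 (range 0.461 to 0.531) in the simulated draws. The covariance was 0.0212 against a simulated 0.0083, a difference of 0.0129. The share of genes with the same sign was 64.3%, against 66.7% simulated. The draws gave every group the same spread, while scramble replicates varied more (median SD 0.109 against 0.036 with shRNA1 and 0.045 with shRNA2). They therefore cannot decide whether the shared calls, r or the covariance exceed those of unchanged groups. A split of the 2 scramble libraries would leave 1 for each hairpin and was not made, so part of any excess may come from the shared controls.

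**Figure D2:**
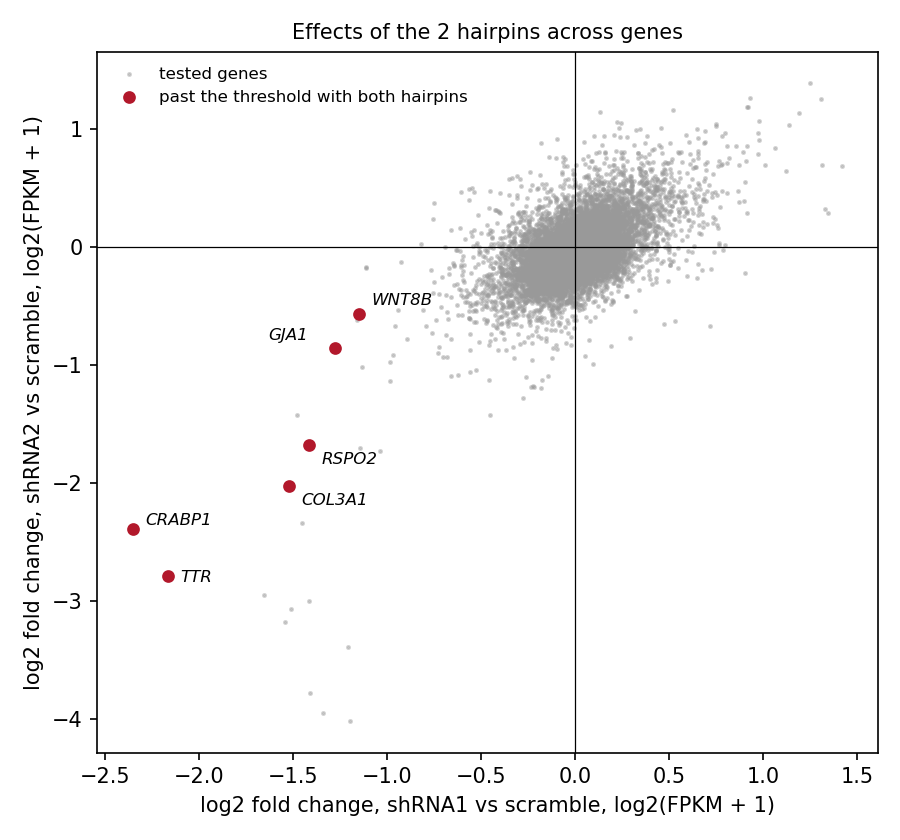
Log2 fold changes of log2(FPKM + 1) with shRNA1 (x axis) and shRNA2 (y axis) against scramble for 18162 genes; red points are the 6 genes past the threshold with both hairpins. All 6 lie in the lower left, and r across genes was 0.572.

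When the hairpins were compared directly, lists of neuronal, synaptic and axon guidance genes stood lower with shRNA2 than with shRNA1 by camera, and those of cell cycle, pluripotency and extracellular matrix genes stood higher, but 0 lists passed with an estimated correlation (camera, smallest adjusted p = 0.0582). No single gene passed (0 higher and 0 lower, smallest adjusted p = 0.0965 with limma and Benjamini-Hochberg adjustment), while 2929 had an unadjusted p under 0.05. Since the spread was shared with the more variable scramble libraries, this count is not comparable with those against scramble. By comparison, voom on recovered reads called 63 higher and 289 lower genes, and protein-coding genes tested alone gave 39 and 206. More genes passed without either scramble library. Leaving one out keeps each gene's fold change between the hairpins as it was, and changes the estimate of the spread and the set of genes tested. The lower genes with the smallest p were BCL11B (-1.01, adjusted p = 0.0965), EEF1A1 (-0.96), EBF1, a transcription factor gene (-0.74), SYT4 (-0.87) and RELN, which encodes the migration cue reelin (-0.58), the last 4 at an adjusted p of 0.0976 each. The higher genes with the smallest p included WNT8B (0.59), LIN28A (0.81), CAPN6 (0.54) and DPPA4 (0.72), at 0.0976 each. RTN4 differed by -0.14 between the hairpins (adjusted p = 0.295) and PABPC1 by -0.07 (adjusted p = 0.618), the latter positive under median-of-ratios scaling (0.017), quantile normalization (0.006) and length correction (0.015).

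Of 26 presynaptic genes, 17 were lower with shRNA2 than with shRNA1 when adjusted over the list alone, including SYT4, SNAP91 (-0.33), SV2A (-0.56) and SNAP25 (-0.39). The list had a median difference of -0.33 (camera adjusted p = 1.92e-10; adjusted p = 0.114 with an estimated correlation). The same held for 17 of 26 pan-neuronal markers (median -0.21, camera adjusted p = 1.45e-07; adjusted p = 0.263 with an estimated correlation), among them GAP43, a growth cone protein gene (-0.30), and DCX, the doublecortin gene of migrating neurons (-0.32). Of 36 axon guidance genes, 1 was higher and 18 were lower (median -0.20, camera adjusted p = 8.48e-06; adjusted p = 0.114 with an estimated correlation), and of 25 postsynaptic genes 6 were lower (-0.23, 1.44e-05; adjusted p = 0.118). Of 13 ventral forebrain and interneuron markers, 6 were lower, among them GAD1, GAD2, DLX5 and DLX6 (list median -0.32, camera adjusted p = 0.000266; adjusted p = 0.539 with an estimated correlation). Of 38 cell cycle genes, 7 were higher, with CCNB2 at 0.34 and CDC6 at 0.32. Of all 38, 37 had positive values (median 0.17, camera adjusted p = 2.89e-18; adjusted p = 0.0582 with an estimated correlation). Of 6 pluripotency markers, 4 were higher (0.36, 1.45e-07; adjusted p = 0.114 with an estimated correlation), and of 20 extracellular matrix genes 7 were higher and 2 lower (0.12, 0.000245; adjusted p = 0.263 with an estimated correlation). These member counts are adjusted over the list alone; over all genes no member passed.

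**Figure D3:**
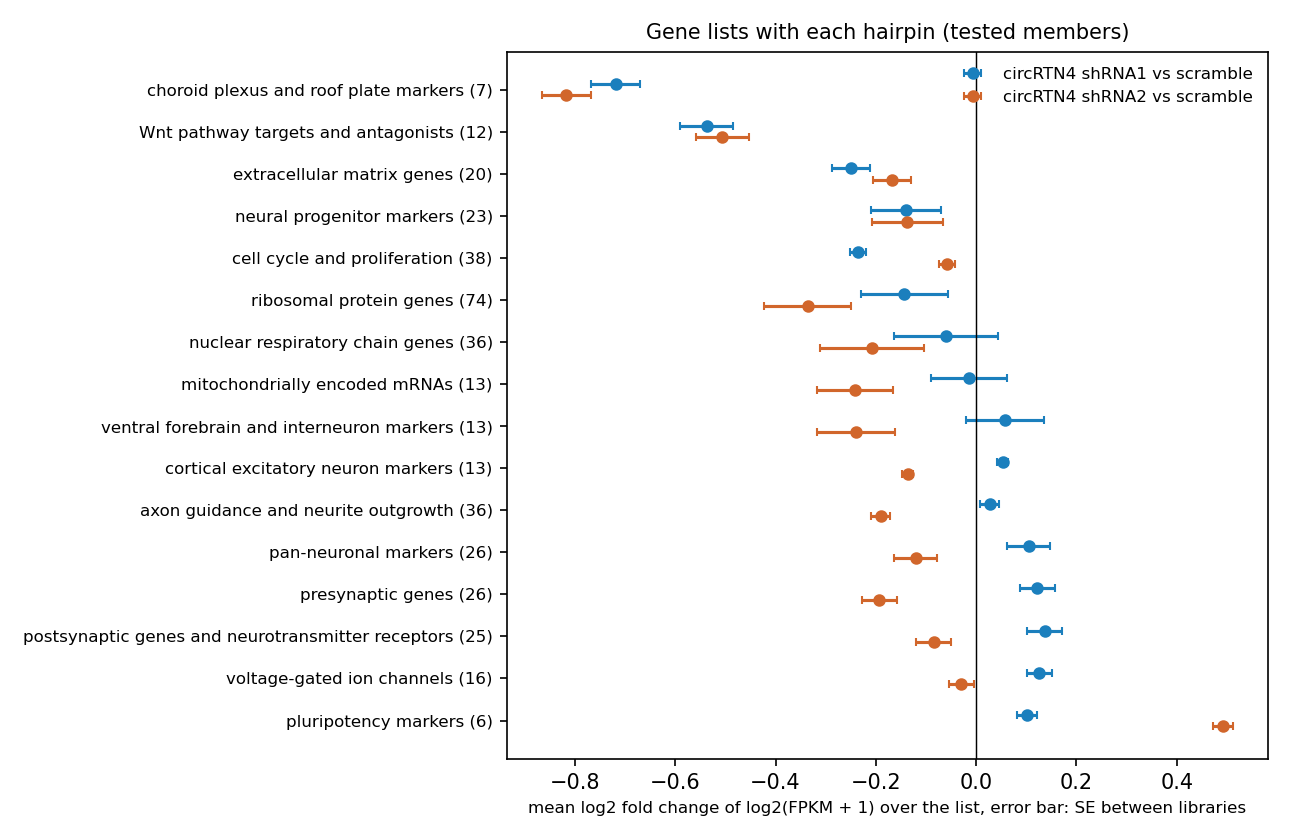
Mean log2 fold change of log2(FPKM + 1) over the tested members of 16 gene lists (number of members in brackets) with shRNA1 and shRNA2 against scramble; points are means over the list and bars are the SE between libraries. Presynaptic genes lie at 0.122 with shRNA1 and -0.193 with shRNA2, and choroid plexus and roof plate markers at -0.719 and -0.817.

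Ribosomal protein genes were lower with shRNA2 than with shRNA1 in all 74 cases, with a median of -0.20 and 0 passing over the list alone (camera adjusted p = 1.92e-10; adjusted p = 0.643 with an estimated correlation). The other lists called as lower were cortical excitatory neuron markers (-0.14, 4 of 13 lower when adjusted over the list alone), ion channel genes (-0.20, 1 higher and 4 lower of 16) and immediate early genes (-0.31, 4 of 6). They were also cholesterol synthesis (-0.12, 0 of 22), nuclear respiratory chain genes (-0.15, 0 of 36) and mitochondrially encoded mRNAs (-0.23, 0 of 13, but 0.014 after quantile normalization). Replication-dependent histone genes were called as higher (0.12, 0 of 28). The adjusted p of these 7 lists with an estimated correlation lay between 0.263 and 0.693. Neural progenitor markers were not called (median 0.04, camera adjusted p = 0.101), with 3 higher and 3 lower when adjusted over the list alone. In all, 16 lists were called, 12 lower and 4 higher, and fry called 12. Fewer were called among genes with a mean of at least 5 FPKM. The call of the cortical excitatory neuron markers was lost without scramble replicate 1 or 2 (camera adjusted p = 0.196 and 0.0799), shRNA1 replicate 2 (0.0521) or shRNA2 replicate 1 (0.0542). Without shRNA1 replicate 1 the calls of voltage-gated ion channels (0.0765), cholesterol synthesis (0.069) and mitochondrially encoded mRNAs (0.0712) were lost. Without shRNA1 replicate 2 those of immediate early genes (0.0723) and mitochondrially encoded mRNAs (0.0504) were lost, and without shRNA2 replicate 1 those of voltage-gated ion channels (0.0515) and mitochondrially encoded mRNAs (0.131). Neural progenitor markers were called as higher without scramble replicate 1 (0.0435) or 2 (0.0256).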

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

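The tests of other cortical hem genes, of the share of neurons, of pseudogene reads and of 5' TOP mRNAs were chosen only after the result was seen. The following gene lists differed between the hairpins when shRNA2 was set directly against shRNA1 (camera, 33 lists, n = 2 libraries each). Median differences were -0.328 for presynaptic genes, -0.209 for pan-neuronal markers, -0.203 for axon guidance and neurite outgrowth, -0.225 for postsynaptic genes and neurotransmitter receptors, -0.2 for voltage-gated ion channels, -0.32 for ventral forebrain and interneuron markers and -0.142 for cortical excitatory neuron markers. They were -0.31 for immediate early genes, -0.122 for cholesterol synthesis, -0.23 for mitochondrially encoded mRNAs, -0.153 for nuclear respiratory chain genes and -0.197 for ribosomal protein genes. Positive differences were 0.173 for cell cycle and proliferation, 0.117 for extracellular matrix genes, 0.36 for pluripotency markers and 0.115 for replication-dependent histone genes. With an estimated correlation 0 of the 16 lists passed, the smallest adjusted p being 0.0582 for cell cycle and proliferation; fry called 12 of 33 lists.

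Lists of choroid plexus, roof plate and Wnt genes had negative medians with both hairpins, but did not pass with an estimated correlation (camera adjusted p = 0.198 with shRNA1 and 0.51 with shRNA2 for each list). That setting called a shifted simulated list in 0 of 10 draws, so not passing it decides little. With fry in the knockdown the adjusted p was 0.00429 for the choroid plexus and roof plate list and 0.00534 for the Wnt list. It was 0.411 for histone genes and 0.213 for nuclear respiratory chain genes. fry does not compare a list with other genes, and p-values against scramble tended to be too small. Scaling of the libraries is argued against, since over 3 scalings the median of the choroid plexus and roof plate list nearest to 0 was -0.419 (spread 0.029), and 1 scramble library out of place is argued against by -0.249 (spread 0.032) without scramble replicate 2, although the call of the list was then lost (camera adjusted p = 0.0563), and with shRNA2 it was lost without scramble replicate 1 (0.127) or 2 (0.173). Fewer choroid plexus or hem cells in the knockdown cultures may account for the fall: 8 other genes of these cells had a median of -0.156 (spread 0.104), 5 of them negative, which decides nothing. An effect of the circRTN4 knockdown itself stays open and untested, and both hairpins were set against the same scramble libraries.

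Lists of neuronal and synaptic genes moved apart between the hairpins, while 0 genes passed with limma and the lists did not pass with an estimated correlation (camera adjusted p = 0.114 for presynaptic genes and 0.263 for pan-neuronal markers). Scaling is argued against by a presynaptic median difference of -0.255 (spread 0.015), the nearest to 0 of 2 scalings, and gene length bias by -0.253 (spread 0.025) after length correction. A different share of neurons and dividing progenitors in the cultures could account for it: the cell cycle list differed by 0.173 (spread 0.016), but the progenitor list had a median of 0.041 with members going both ways, so this was not decided. A different action of the hairpins on other transcripts was not tested.

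The ribosomal protein genes had negative medians with both hairpins, but did not pass with an estimated correlation (camera adjusted p = 0.368 with shRNA1 and 0.51 with shRNA2), and with shRNA1 0 of 74 passed with limma; the median with shRNA1 was -0.06 without scramble replicate 2 and -0.07 after quantile normalization, and in the knockdown -0.12 after quantile normalization. Gene length bias is argued against by a median of -0.2 (spread 0.05) after length correction. Reads moving to pseudogene copies are argued against, since reads on ribosomal protein pseudogenes did not rise. They changed by -133 RPM (SE 60) while those on the genes changed by -1314 RPM (SE 401). Without scramble replicate 2, which was the highest, these changes were -50 RPM and -754 RPM. A change of 5' TOP mRNAs as a class is a candidate explanation. Over 38 other such mRNAs the median was -0.16 (spread 0.025), and 37 were negative. The values of some of these had been seen before the list was written. Over 28 that were in no fixed list and not seen before, the median was -0.157, with 27 negative. The median of all tested genes was -0.034, and -0.078 among genes with a mean of at least 5 FPKM. Some other lists were about as low in the knockdown. Cell cycle genes had a median of -0.157 (37 of 38 negative), mitochondrially encoded mRNAs -0.136 (13 of 13) and nuclear respiratory chain genes -0.131 (35 of 36). Others lay near or above 0, such as pan-neuronal markers (-0.002) and postsynaptic genes (0.029). The fall was therefore not particular to 5' TOP mRNAs. An effect of the circRTN4 knockdown on translation was not tested.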

How the results depend on the processing

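The voom, protein-coding, length correction and crossed block alternatives were chosen after the data were seen. Of 207 comparison results under alternatives, 120 kept their direction and side of the threshold, 57 were weaker, 28 stronger, 2 moved and 0 reversed; of 929 list results, 797 kept both, 124 were weaker and 8 reversed. A lone scramble library was assumed to vary like the other groups. The alternative planned for a table of counts was not run, since the table holds FPKM. The cause of the changes below was not tested unless fewer genes or libraries were used.

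Counts of genes changed, circRTN4 knockdown vs scramble (15): no filter on low values 0, mean of at least 5 FPKM 35, median-of-ratios scaling 28, quantile normalization 30, replicate block 1, crossed replicate block 1, voom on recovered reads 167, protein-coding genes only 102, gene length trend removed 28, a log2 fold change of at least 1 7, the 4 libraries as one group 7, leaving out 1 library 0 to 494. Of genes changed, shRNA1 vs scramble (6): pseudocount 0.1 2, no filter 0, 5 FPKM 3, replicate block 0, crossed 0, voom 20, protein-coding 22, only 2 groups 0, leaving out 1 library 0 to 1. Of genes changed, shRNA2 vs scramble (114): no filter 0, 5 FPKM 261, quantile 71, replicate block 0, crossed 0, no variance trend 35, robust hyperparameters 48, voom 498, protein-coding 383, length 73, a log2 fold change of at least 1 20, only 2 groups 1, leaving out 1 library 0 to 2412. Of genes changed, shRNA2 vs shRNA1 (0 with limma, 2929 at an unadjusted p under 0.05): 5 FPKM 46, voom 352, protein-coding 245, only 2 groups 957, leaving out 1 library 0 to 1010. Shared by both hairpins (6): pseudocount 0.1 2, no filter 0, 5 FPKM 3, replicate block 0, crossed 0, no variance trend 3, voom 18, protein-coding 19, adjusted in one and unadjusted in the other 74, leaving out 1 library 0 to 1. The correlation (0.572) ranged from 0.483 to 0.744 on leaving out 1 library. The replicate numbers did not pair the libraries (correlations -0.01, -0.15 and 0.01).

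Lists called: knockdown (12) no filter 22, 5 FPKM 4, estimated correlation 0; shRNA1 (22) 5 FPKM 10, estimated correlation 1, fry 14; shRNA2 (9) no filter 27, 5 FPKM 2, protein-coding 5, estimated correlation 0, fry 22; shRNA2 against shRNA1 (16) 5 FPKM 10, estimated correlation 0. RTN4 in the knockdown (-0.256) was -0.261 with voom (adjusted p = 0.0407) and -0.289 to -0.223 on leaving out 1 library. A list counts as reversed where camera turned; only the median turned for histone genes with shRNA1 without scramble replicate 2 (0.012) and cytosolic heat shock with shRNA1 under quantile (0.002). Reversed: with 5 FPKM, forebrain patterning factors 0.035 and Notch pathway -0.015 with shRNA1, and axon guidance and neurite outgrowth -0.146 with shRNA2, where camera turned; PABPC1 between hairpins 0.017 (median-of-ratios), 0.006 (quantile) and 0.015 (length); mitochondrially encoded mRNAs under quantile 0.028 with shRNA2 and 0.014 between hairpins; on leaving out 1 library, of which the highest is without scramble replicate 2 and the lowest without scramble replicate 1, Notch pathway -0.249 to 0.13 and nuclear respiratory chain genes -0.188 to 0.069 with shRNA1, and replication-dependent histone genes -0.409 to 0.045 in the knockdown.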

Other observations

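The lists in this part were chosen only after their values were seen. Protocadherin beta genes, which encode clustered adhesion proteins of neurons, had positive values in the knockdown for 13 of 13 members, with a median log2 fold change of 0.15 (0.12 with shRNA1 and 0.24 with shRNA2). With shRNA2, 1 passed over all genes. The 3 ONECUT transcription factor genes had a median of 0.33 in the knockdown, with 0 passing over all genes (limma, Benjamini-Hochberg adjustment).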
